A study of Mus musculus with 18 samples.

How the data were processed

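Testis RNA of 18 samples was sequenced, 3 in each of 6 groups, and the groups and replicate numbers were taken from the labels. Per the labels' protocols, testes were frozen in liquid nitrogen, RNA was extracted with Trizol and a column kit, and libraries were made from total RNA by the standard Illumina route. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm10 were used. The counting tool, the gene annotation and the use of strand were not given in the sources used here. The authors deposited 1 table of RPKM values per gene symbol and sample, rounded to hundredths, and whether fragments or reads were counted was not stated. RPKM divides a gene's reads by its length and by the library's total, so a change in abundant transcripts or in the yield of long transcripts moves the values of all others. Overlapping, antisense and near-identical genes could not be told apart from these values.

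The table held 20985 rows. The 3 symbols that stood on 6 rows were left out, which left 20979 genes, and 384 of these were at 0 in every library. A further 22 rows had been turned into dates by a spreadsheet, and no gene was named from them. Depth was estimated from the steps between low RPKM values, which are whole multiples of the value of 1 read. These steps gave 12500000 to 13197000 reads per library. Only implied depths inside a fixed window were kept, which bounds the result in advance. This range therefore does not show that depth was equal between groups. Values were transformed as log2(RPKM + 1), and the 13874 genes with at least 1 RPKM in at least 3 libraries were tested.

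Differences were tested with limma 3.58.1 in R 4.3.3, with a trend of the prior variance on the mean, 1 coefficient for each of the 6 groups over all 18 samples, 12 residual and 3.71 prior degrees of freedom, and two-sided tests. p-values were adjusted by the method of Benjamini and Hochberg within a comparison, with a threshold of 0.05. The planned comparisons were 6 contrasts of 2 groups and the interaction of AOS with the diet and STZ. The plan held a count test and a test for normalized values, and the latter was used because the table held RPKM. The main effects of HFD_STZ and of AOS, which set 6 samples against 6, and the F test among the 6 groups were added after the planned results had been seen.

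The plan also fixed 31 gene lists, of which 30 had at least 5 tested members. They were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, and were adjusted over the lists of a comparison. Members were counted as called over all genes and also adjusted over the list alone. The return towards control was tested on the covariance of fold changes across genes, less the part from shared libraries, with 100 regroupings of the libraries' deviations.

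Genes to be named were chosen by a rule set before the data were examined. For each comparison these were up to 8 risen and up to 8 fallen genes with the largest log2 change among those past the threshold, with groups that did not overlap and a mean of at least 1 RPKM in the higher group. Where fewer than 5 passed in a direction, up to 5 genes with the smallest p were taken instead and are given as not passing. The rule added the 3 members with the smallest p of each called list and the panel Star, Cyp17a1, Insl3, Sycp3, Stra8, Prm1, Tnp1, Amh, Cldn11 and Cd68. Some genes that the rule chose are not reported here, and the counts include them.

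The alternatives planned were scaling of the libraries by median ratios, no filter on low values, a pseudocount of 0.1, a fit on only the groups of a comparison, the replicate number as a block, robust empirical Bayes and the omission of each library in turn. The replicate omission was extended to the gene lists after the data had been seen. Also chosen after seeing the data were the removal of each library's trend on transcript length (a lowess curve with a span of 0.3) and the omission of 4 libraries high in Crisp1. Transcript lengths and coordinates came from the GENCODE vM21 annotation of GRCm38/mm10. Of the symbols 96.4% matched the annotation, and 13578 of the tested genes (97.9%) had a length.

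The tests were checked on simulated values with 200 changed genes among 13874. For HFD_STZ against control, 83.6%, 95.5% and 100% of the genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 8 unchanged genes called. For the main effect of HFD_STZ these shares were 95.5%, 97.0% and 100%, with 6 unchanged genes called. The simulated genes varied independently of each other, unlike real ones. The changed genes were drawn only from genes above a set mean level, so these shares do not hold for low genes. A simulated list of 20 genes, each raised by 0.3 on the log2 scale, was called by camera with an adjusted p of 1.14e-24, and 0 of 20 unchanged lists were called. Tables and plots were also made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.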

Results

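The series asked how transfer of gut microbiota acts on a testis damaged by a high fat diet with STZ. RNA sequencing was done on the testes of ICR mice, an outbred laboratory stock, aged 10 weeks. The 18 libraries fell into 6 groups of 3, named here as control, AOS, HFD_STZ, HFD_STZ_AOS, HFD_STZ_AOS_FMT and HFD_STZ_control_FMT. HFD_STZ stands for a high fat diet with STZ (streptozotocin, a toxin of the insulin-producing cells), and AOS is an abbreviation that the labels give with a dose of 10 mg/kg. FMT stands for the transfer of fecal microbiota, from AOS donors or from control donors. The deposited RPKM values summed to between 588160 and 646910 per library, and 13022 to 13490 genes reached 1 RPKM. Depths estimated from the steps between low values, inside the fixed window, were 12500000 to 13197000 reads per library, with a median of 12908200. Libraries of 1 group had Pearson correlations across genes of 0.988 to 0.995, against 0.984 to 0.994 for libraries of different groups, and genes are not independent replicates. No label said that the libraries came from separate animals, so p-values measured the spread between these samples, which may be technical. Levels are given as mean ± SD over 3 libraries unless another n is stated. Fold changes are on the log2(RPKM + 1) scale with their standard error, and they understate the change of low genes.

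The effect of the diet with STZ was read from HFD_STZ against control. Fitm1, which encodes a protein of lipid droplet formation, was at 17.0 ± 3.2 RPKM in HFD_STZ and 5.80 ± 1.1 in control (n = 3 each), a log2 difference of 1.40 ± 0.23. Arg2, an arginase of mitochondria, was at 9.12 ± 2.2 against 3.40 ± 1.3 RPKM. Sec23a, a coat protein of the secretory pathway, was at 34.8 ± 0.53 against 45.6 ± 0.92 RPKM, a log2 difference of -0.38 ± 0.06. None of these passed limma's test over all genes, where the adjusted p was 0.0661 for Sec23a, 0.143 for Fitm1 and 0.226 for Arg2. Of the 13874 genes tested, limma called 0, while 1151 had an unadjusted p under 0.05 and 693.7 were expected by chance. The germ cell and somatic markers Star, Insl3, Sycp3, Stra8, Prm1, Tnp1, Amh and Cd68 had adjusted p values of 0.860 or more. Cyp17a1, a steroid hydroxylase of Leydig cells, stood at 289 ± 16 against 348 ± 36 RPKM with an adjusted p of 0.602. Cldn11, a tight junction protein of Sertoli cells, stood at 37.5 ± 0.57 against 33.1 ± 0.93 RPKM with an adjusted p of 0.589.

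Among 30 gene lists fixed in advance, limma's camera test with a preset correlation called 6 in HFD_STZ against control. Interferon response genes were higher in 14 of 14 members, with Psmb8 at 2.85 ± 0.73 against 1.09 ± 0.46 RPKM and Oasl1 at 1.06 ± 0.13 against 0.490 ± 0.16 RPKM. The list had an adjusted p of 0.00104, and adjusted p = 0.690 with an estimated correlation. Fatty acid oxidation genes were higher in 17 of 19 members, among them Cpt1b, a carnitine transferase (log2 difference 0.11 ± 0.03). Their adjusted p was 0.00513, and adjusted p = 0.690 with an estimated correlation. Sertoli cell genes were higher in 25 of 28 members, among them Gata1 at 5.16 ± 0.32 against 4.02 ± 0.38 RPKM, with an adjusted p of 0.00513 and adjusted p = 0.690 with an estimated correlation. Cholesterol biosynthesis genes were lower in 19 of 24 members, with Sc5d at 6.5 ± 0.72 against 9.07 ± 1.0 RPKM, at an adjusted p of 0.00131 and adjusted p = 0.690 with an estimated correlation. Round spermatid genes were lower in 22 of 30 members and elongating spermatid genes in 21 of 29, each with an adjusted p of 0.00152. With an estimated correlation, adjusted p = 0.690 for the former and adjusted p = 0.746 for the latter, and the medians of both lists were only -0.03 on the log2 scale. limma called 0 members of these 6 lists over all genes. Adjusted over the list alone, 2 interferon genes (Psmb8 and Oasl1) and 2 fatty acid genes (Cpt1b among them) passed, and unadjusted p values under 0.05 were found for 3 interferon, 4 fatty acid, 4 Sertoli, 3 cholesterol, 1 round spermatid and 3 elongating spermatid genes. Single libraries carried several of these list calls. The adjusted p became 0.0747 for interferon genes without HFD_STZ replicate 2, 0.0951 for fatty acid oxidation without HFD_STZ replicate 3, 0.0769 for cholesterol genes without HFD_STZ replicate 1 and 0.102 for elongating spermatid genes without control replicate 1. The Sertoli list lost its call without control replicate 2 (0.0915), control replicate 3 (0.0737) or HFD_STZ replicate 2 (0.0747).

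A main effect of HFD_STZ, the mean of HFD_STZ and HFD_STZ_AOS against the mean of control and AOS, was added after the 6 comparisons of 2 groups had given 0 to 3 genes each. Fitm1 rose to 20.9 ± 8.6 from 7.09 ± 1.7 RPKM (n = 6 each), a log2 change of 1.39 ± 0.17 with an adjusted p of 0.00479. Cyp21a1, a steroid hydroxylase of adrenal hormone synthesis, rose to 7.75 ± 1.4 from 3.52 ± 0.85 RPKM, by 0.96 ± 0.17 with an adjusted p of 0.0129. It has a near-identical pseudogene, so its counts are uncertain. The membrane mucin gene Muc15 rose by 0.93 ± 0.17 and the villin-like gene Vill by 0.76 ± 0.14, each with an adjusted p of 0.0150. Hap1, a gene of intracellular transport, rose by 0.64 ± 0.11 with an adjusted p of 0.0114. Arl9, a small GTPase of the ARF family, fell to 79.6 ± 2.7 from 97.2 ± 5.8 RPKM, with a log2 change of -0.28 ± 0.04 and an adjusted p of 0.00789. Shisa3 fell to 13.6 ± 1.1 from 16.7 ± 0.80 RPKM, and Pcdha12 to 1.01 ± 0.29 from 2.02 ± 0.22 RPKM, each with an adjusted p of 0.00789. Pcdha12 shares exons with other protocadherins, so its counts are uncertain. Fitm1 lies on chromosome 14 at 55575617 to 55576954, Cyp21a1 on chromosome 17 at 34801348 to 34804561 and Arl9 on chromosome 5 at 77004055 to 77010606, each a protein-coding gene of GRCm38/mm10.

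**Figure D1:**
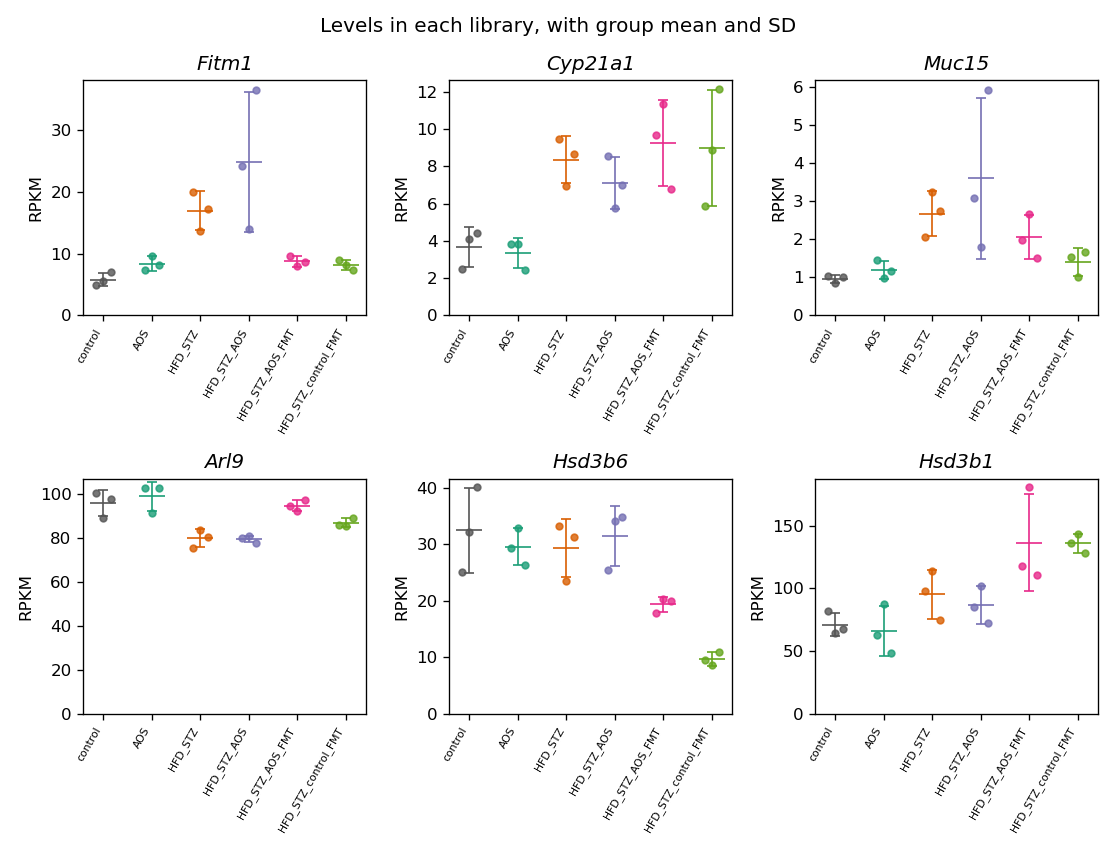
RPKM on the vertical axis of Fitm1, Cyp21a1, Muc15, Arl9, Hsd3b6 and Hsd3b1 in each of the 18 libraries by group, where points are libraries, long bars are group means and whiskers are the SD (n = 3). The HFD_STZ and HFD_STZ_AOS libraries of Fitm1 lay between 13.64 and 36.52 RPKM, above all control and AOS libraries, and Hsd3b6 was lowest in HFD_STZ_control_FMT at a mean of 9.69 RPKM.

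limma called 396 genes for this main effect, 333 higher and 63 lower, and 2603 had an unadjusted p under 0.05. With libraries scaled by median ratios the call count was 268, of which 163 were higher and 105 lower, and with the length trend removed it was 315, of which 173 were higher and 142 lower. Fitm1, Arl9, Pcdha12, Shisa3, Muc15 and Vill stayed past the threshold in all 20 other settings. Other genes that the rule chose for their large change, not reported here, missed the threshold in 1 to 13 of these settings. Cyp21a1 and Hap1 missed it only without the 4 libraries high in epididymal Crisp1, with adjusted p values of 0.0551 and 0.0618, and the count of called genes was then 36. The count rose to 695 without HFD_STZ_AOS replicate 2. It dropped to 129, 151 and 180 without control replicates 1, 2 and 3, to 157 and 122 without AOS replicates 1 and 3, to 110 and 136 without HFD_STZ replicates 1 and 3, and to 124 without HFD_STZ_AOS replicate 3.

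For the same main effect, camera with the preset correlation called 7 lists. Fatty acid oxidation genes were higher in 17 of 19 members, with an adjusted p of 0.000577 and adjusted p = 0.741 with an estimated correlation. Of them, 4 rose over all genes (among them Decr1 at 0.33 ± 0.08 and Acadl at 0.26 ± 0.07) and 7 passed adjusted over the list alone. Sertoli cell genes were higher in 23 of 28 members, with an adjusted p of 0.00871 and adjusted p = 0.741 with an estimated correlation. The defensin gene Defb19 rose from 247 ± 15 to 286 ± 26 RPKM, the 1 member called over all genes, and 9 passed adjusted over the list alone. Round spermatid genes were lower in 21 of 30 members and elongating spermatid genes in 19 of 29, each with an adjusted p of 0.000577 and adjusted p = 0.741 with an estimated correlation. In each of these lists 1 member fell, both over all genes and adjusted over the list alone: the acrosin gene Acr, by -0.13 ± 0.03, and the carbonic anhydrase gene Car2, by -0.23 ± 0.05. Ribosomal protein genes were higher in 28 of 32 members, with an adjusted p of 0.00871, adjusted p = 0.809 with an estimated correlation, 1 member called over all genes and 2 adjusted over the list alone, and with the length trend removed the adjusted p was 0.145. Extracellular matrix genes were higher in 19 of 19 members, with an adjusted p of 0.0476, adjusted p = 0.809 with an estimated correlation and 2 members (Lum and Fn1) adjusted over the list alone. limma called 0 of them over all genes and 6 had an unadjusted p under 0.05. Cilium genes were lower in 19 of 27 members, with an adjusted p of 0.0390 and adjusted p = 0.741 with an estimated correlation, although the 1 member called over all genes, Spag16, rose by 0.11 ± 0.03. The 2 cilium members that passed adjusted over the list alone, Spag16 and Armc4, were both higher. Without the 4 libraries high in Crisp1 the adjusted p was 0.0757 for round spermatid genes and 0.266 for extracellular matrix genes. The single calls of Decr1, Acadl, Defb19, Acr, Car2 and Spag16 were not kept in 12 to 15 of the 20 other settings. These settings included the omission of AOS replicate 1, AOS replicate 3, HFD_STZ replicate 1 or HFD_STZ replicate 3 for each of the 6 genes, with adjusted p values of 0.0607 to 0.121.

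With 1 library left out, the list counts of this main effect changed as follows. Without HFD_STZ replicate 3 camera called 4 lists, and the adjusted p was 0.108 for ribosomal protein genes, 0.0711 for extracellular matrix genes and 0.125 for cilium genes. Without HFD_STZ_AOS replicate 3 it was 0.0534 for round spermatid genes, 0.294 for extracellular matrix genes and 0.138 for cilium genes. Extracellular matrix and cilium genes were at 0.0782 each without control replicate 1, at 0.0937 and 0.0924 without AOS replicate 3, and at 0.129 and 0.0534 without HFD_STZ replicate 2. Cilium genes were at 0.0722 without control replicate 2, and extracellular matrix genes at 0.0513 without HFD_STZ_AOS replicate 2.

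What AOS did without the diet was read from AOS against control. Sc5d and Msmo1, enzymes of cholesterol synthesis, were at 6.20 ± 1.1 against 9.07 ± 1.0 and at 14.1 ± 1.3 against 22.6 ± 2.1 RPKM. The Leydig cell enzymes Cyp11a1 and Cyp17a1 were at 91.7 ± 16 against 133 ± 15 and at 255 ± 31 against 348 ± 36 RPKM. Tnp2, a transition protein of sperm chromatin, was at 15548 ± 407 against 12372 ± 850 RPKM, a log2 difference of 0.33 ± 0.08. limma called 0 genes, the smallest adjusted p was 0.161, and 1923 genes had an unadjusted p under 0.05. Without AOS replicate 2 it called 3 genes, all higher, with Rps29 (log2 difference 0.78 ± 0.19 with all libraries) among them at 0.0249.

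In AOS against control, camera with the preset correlation called 8 lists. Cholesterol biosynthesis genes were lower in 21 of 24 members, with an adjusted p of 3.05e-05 and adjusted p = 0.552 with an estimated correlation, and 10 passed adjusted over the list alone. Elongating spermatid genes were higher in 22 of 29 members, with an adjusted p of 1.91e-05, adjusted p = 0.552 with an estimated correlation and 5 members adjusted over the list alone, among them Tnp1, Tnp2 and Prm3. Interferon genes were higher in 12 of 14 members, with an adjusted p of 0.000717 and adjusted p = 0.552 with an estimated correlation, and adjusted over the list alone 0 passed in limma's test. Oxidative phosphorylation genes were higher in 25 of 34 members at an adjusted p of 0.000189, and adjusted p = 0.552 with an estimated correlation. Ribosomal protein genes were higher in 21 of 32 members at 0.000238, and adjusted p = 0.615 with an estimated correlation, with 3 members (Rps29, Rpl13 and Rpl27) adjusted over the list alone. Leydig cell genes were lower in 17 of 20 members at 0.0171, meiosis genes in 29 of 38 at 0.0209 and cilium genes in 21 of 27 at 0.0119. With an estimated correlation these gave adjusted p = 0.671, adjusted p = 0.552 and adjusted p = 0.552. Adjusted over the list alone, Cyp17a1 and Cyp11a1 passed in the Leydig list and Sycp2 and Sycp1, proteins of the synaptonemal complex, in the meiosis list. In limma's test over all genes 0 members of the 8 lists passed. Unadjusted p values under 0.05 were found for 10 cholesterol, 9 elongating spermatid, 4 interferon, 9 oxidative phosphorylation, 8 ribosomal, 4 Leydig, 10 meiosis and 6 cilium genes. The Leydig list lost its call without control replicate 1 (0.0569), control replicate 3 (0.0978), AOS replicate 1 (0.114) or AOS replicate 3 (0.236). The meiosis list lost it without control replicate 2 (0.0862) or AOS replicate 1 (0.114), the interferon list without AOS replicate 3 (0.329) and the cilium list without control replicate 1 (0.0914). With the transcript-length trend removed, the adjusted p was 0.397 for oxidative phosphorylation, 0.549 for ribosomal and 0.289 for cilium genes.

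What AOS did on the diet with STZ was read from HFD_STZ_AOS against HFD_STZ. Tap1, a transporter of antigen peptides, was at 0.923 ± 0.34 against 5.08 ± 1.7 RPKM, a log2 difference of -1.64 ± 0.38, and the proteasome subunits Psmb9 and Psmb8 were at 1.06 ± 0.49 against 4.11 ± 0.71 and at 1.12 ± 0.21 against 2.85 ± 0.73 RPKM. Myl6, a myosin light chain, was at 119 ± 3.4 against 97.6 ± 4.3 RPKM and Rpl13 at 502 ± 29 against 424 ± 20 RPKM. Wdr60, a gene of intraflagellar transport, was at 26.3 ± 1.8 against 33.8 ± 1.3 RPKM. Adjusted p values were 0.0805 for Myl6 and Wdr60, 0.170 for Tap1 and Rpl13 and 0.199 for Psmb9 and Psmb8. limma called 0 genes and 1734 had an unadjusted p under 0.05. Without the 4 libraries high in Crisp1 it called 2 genes, among them the predicted gene Gm21366 with an adjusted p of 0.0276.

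For AOS on the diet with STZ, camera with the preset correlation called 7 lists. Ribosomal protein genes were higher in 29 of 32 members, with an adjusted p of 2.12e-14, adjusted p = 0.244 with an estimated correlation and 19 members adjusted over the list alone. Oxidative phosphorylation genes were higher in 31 of 34 members at 4.58e-07, and adjusted p = 0.423 with an estimated correlation, with Cox4i1 and Ndufb3 passing adjusted over the list alone. Elongating spermatid genes were higher in 24 of 29 members at 4.48e-06, and adjusted p = 0.675 with an estimated correlation. Cilium genes were lower in 22 of 27 members at 4.60e-05, and adjusted p = 0.244 with an estimated correlation, with 8 members, among them Hydin, Cfap65 and Ccdc39, adjusted over the list alone. Interferon genes were lower in 10 of 14 members at 0.0115, and adjusted p = 0.840 with an estimated correlation, and the 3 members that passed adjusted over the list alone were Tap1, Psmb9 and Psmb8. Genes of epididymis, a neighbouring tissue, were higher in 10 of 11 members at 0.00353, and adjusted p = 0.340 with an estimated correlation. Without the 4 libraries high in Crisp1 the epididymis list had an adjusted p of 0.0211, so these libraries alone do not account for the call. Adipose tissue genes were higher in 13 of 13 members at 0.0386, and adjusted p = 0.886 with an estimated correlation. In limma's test over all genes 0 members of the 7 lists passed. Unadjusted p values under 0.05 were found for 22 ribosomal, 10 oxidative phosphorylation, 12 elongating spermatid, 9 cilium, 3 interferon, 2 epididymis and 0 adipose genes. With the length trend removed, the adjusted p was 0.209 for elongating spermatid, 0.301 for oxidative phosphorylation, 0.228 for epididymis and 0.125 for adipose genes. The adipose call was lost without HFD_STZ replicate 3 (0.244) or HFD_STZ_AOS replicate 3 (0.817), a library in which Crisp1 was at 156.69 and Fabp4 at 72.55 RPKM. The interferon call was lost without HFD_STZ replicate 2 (0.246) or HFD_STZ_AOS replicate 2 (0.0596), and without HFD_STZ_AOS replicate 3 camera called 12 lists.

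A main effect of AOS, the mean of AOS and HFD_STZ_AOS against the mean of control and HFD_STZ, was likewise added after the planned comparisons. Rps21, a ribosomal protein gene, rose to 210 ± 18 from 161 ± 14 RPKM (n = 6 each), by 0.38 ± 0.07 with an adjusted p of 0.0235. Tnp1 and Tnp2 rose by 0.25 ± 0.06 and 0.29 ± 0.06, with adjusted p values of 0.0409 and 0.0277, and Cox4i1, a subunit of cytochrome oxidase, by 0.20 ± 0.04 with an adjusted p of 0.0267. Sycp1 fell to 55.6 ± 2.3 from 66.3 ± 4.7 RPKM, with a log2 change of -0.25 ± 0.05 and an adjusted p of 0.0275. Scaper and the acetyltransferase gene Kat2b fell with log2 changes of -0.24 ± 0.04 and -0.31 ± 0.05, each with an adjusted p of 0.0235. Hmgcs1 and Sc5d, enzymes of cholesterol synthesis, fell with log2 changes of -0.27 ± 0.07 and -0.34 ± 0.08 and adjusted p values of 0.0469 and 0.0495. Of 20 other settings, the calls of Sycp1, Scaper and Kat2b were lost in 7 each and that of Rps21 in 8. limma called 325 genes, 180 higher and 145 lower, and 2868 had an unadjusted p under 0.05. With libraries scaled by median ratios the count was 220, of which 152 were higher and 68 lower. These changes ran with transcript length: the Spearman rho across genes of the log2 change with length was -0.387, genes under 1000 bases had a median change of 0.10 and genes over 5000 bases one of -0.07. With that trend removed limma called 0 genes, while 305 of the 318 called genes with a known length still had an unadjusted p under 0.05. The count was 0 without control replicate 2, AOS replicate 1, HFD_STZ replicate 2 or HFD_STZ_AOS replicate 1, 1 without AOS replicate 3, 3 without HFD_STZ replicate 1, 57 without control replicate 1 and 176 without control replicate 3.

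**Figure D2:**
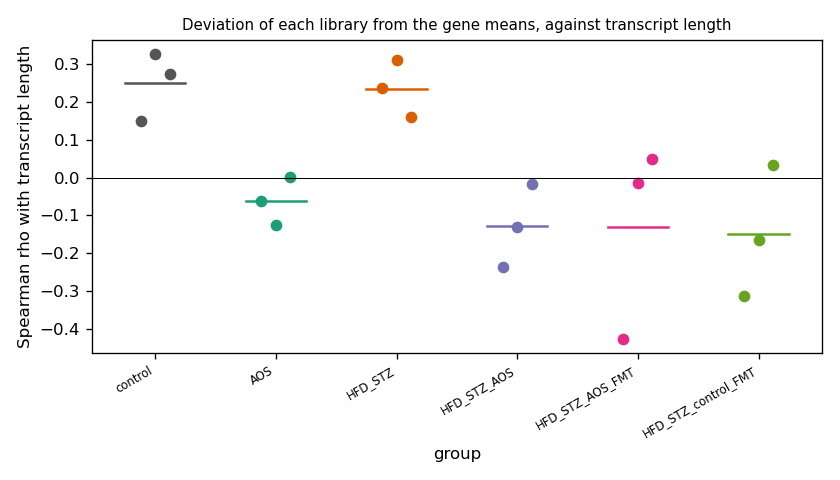
Spearman rho on the vertical axis, across genes within each library, of the deviation from the gene's mean over all libraries with transcript length, for the 18 libraries by group, where points are libraries and bars are group means. The control and HFD_STZ libraries lay between 0.150 and 0.325, and the 12 libraries of the other groups between -0.425 and 0.0476.

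Camera with the preset correlation called 5 lists for the main effect of AOS, none of whose calls was lost with 1 library left out. Ribosomal protein genes were higher in 27 of 32 members (adjusted p 3.79e-11), and adjusted p = 0.395 with an estimated correlation. Over all genes 6 rose, among them Rpl13, Rps29 and Rps18, and 18 passed adjusted over the list alone. Elongating spermatid genes were higher in 23 of 29 members (adjusted p 1.00e-07), and adjusted p = 0.556 with an estimated correlation. Over all genes 4 rose (Tnp2, Prm3, Tnp1 and Gapdhs) and 14 passed adjusted over the list alone. Oxidative phosphorylation genes were higher in 28 of 34 members (adjusted p 1.00e-07), and adjusted p = 0.494 with an estimated correlation. Over all genes 2 rose (Cox4i1 and Cox5a) and 12 passed adjusted over the list alone. Cilium genes were lower in 21 of 27 members (adjusted p 0.000106), and adjusted p = 0.395 with an estimated correlation. Over all genes 2 fell (Cfap43 and Hydin) and 13 passed adjusted over the list alone. Cholesterol biosynthesis genes were lower in 18 of 24 members (adjusted p 0.000451), and adjusted p = 0.571 with an estimated correlation. Over all genes 2 fell (Hmgcs1 and Sc5d) and 8 passed adjusted over the list alone. With the length trend removed, oxidative phosphorylation genes had an adjusted p of 0.304. The medians of the other lists were then 0.404 of their value before for ribosomal, 0.420 for cilium, 0.323 for elongating spermatid and 0.906 for cholesterol genes. The call of Hydin was lost in 17 of the 20 other settings, with an adjusted p of 0.515 and a log2 change of -0.04 when the length trend was removed. The calls of Sc5d, Hmgcs1, Cox5a and Cfap43 were lost in 16, 14, 14 and 9 settings, those of Tnp1, Rps18, Prm3 and Tnp2 in 13, 11, 10 and 9, and those of Cox4i1, Rps29 and Rpl13 in 8, 8 and 7. Without AOS replicate 2 and HFD_STZ_AOS replicate 3 in turn, camera called 8 and 9 lists.

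Whether the difference made by AOS depended on the diet was tested by the interaction, the change from HFD_STZ to HFD_STZ_AOS minus that from control to AOS. Tap1 was at 2.50 ± 1.6 RPKM in control, 5.01 ± 2.2 in AOS, 5.08 ± 1.7 in HFD_STZ and 0.923 ± 0.34 in HFD_STZ_AOS, with an interaction of -2.49 ± 0.53 on the log2 scale. Psmb8 and Psmb9 had interactions of -1.41 ± 0.31 and -1.97 ± 0.48. Their neighbour Tap2, a partner of Tap1, had an interaction of -1.52 ± 0.34. The hydrolase gene Hddc3 was at 9.03 ± 0.51, 6.93 ± 0.20, 9.62 ± 0.57 and 12.1 ± 2.0 RPKM in the same order of groups, with an interaction of 0.63 ± 0.12. limma called 0 genes, with adjusted p values of 0.566 for Tap1 and Psmb8 and 0.495 for Hddc3, and 640 genes had an unadjusted p under 0.05. Camera with the preset correlation called 6 lists, of which the interferon list was the only 1 kept in all 12 fits that left out 1 library. It was lower in 13 of 14 members with an adjusted p of 1.62e-08, and adjusted p = 0.408 with an estimated correlation. Only 3 members (Tap1, Psmb8 and Psmb9) passed adjusted over the list alone, while limma called 0 over all genes and 4 had an unadjusted p under 0.05. These 3 genes and Tap2, which is not on the interferon list, lie side by side on chromosome 17, between 34181987 and 34216321. They may therefore not count as separate members, which was not tested.

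**Figure D3:**
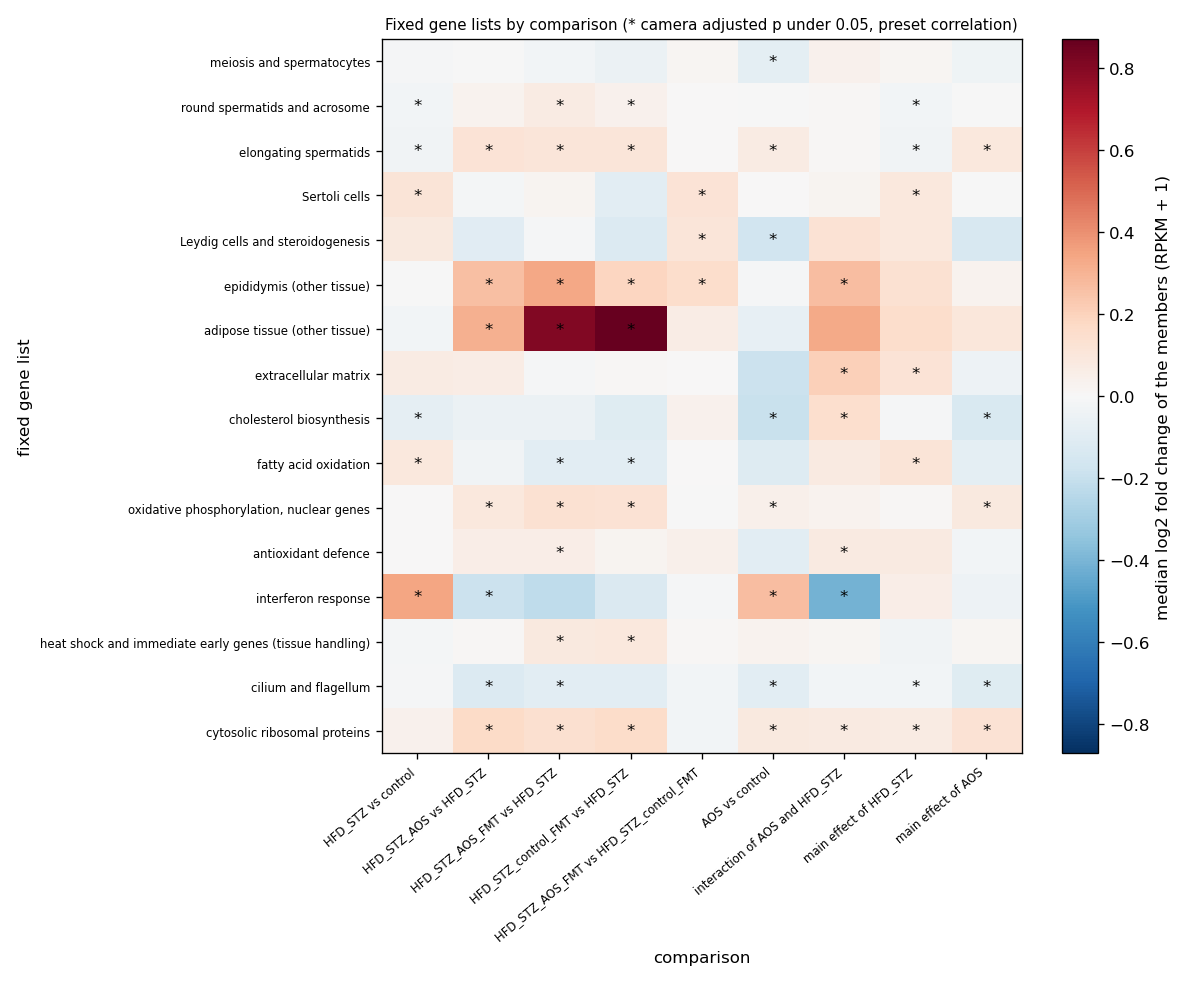
Median log2 fold change of the members (colour scale, red higher and blue lower) for the gene lists in rows with at least 1 call, in the comparisons in columns, where an asterisk marks an adjusted p under 0.05 in camera with a preset correlation. Adipose tissue genes had medians of 0.81 and 0.87 in the microbiota groups against HFD_STZ, and with an estimated correlation camera called 0 lists in each column, where the smallest adjusted p was 0.126.

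The transfer of microbiota from AOS donors was read from HFD_STZ_AOS_FMT against HFD_STZ. Kap, the kidney androgen-regulated protein gene, rose to 33.9 ± 4.6 from 0.293 ± 0.39 RPKM, by 4.79 ± 0.15 on the log2 scale with an adjusted p of 1.30e-11. Tmsb10, a regulator of actin, was at 2404 ± 12 against 1843 ± 110 RPKM and Rcbtb2 at 6.46 ± 0.99 against 3.77 ± 0.52 RPKM, each with an adjusted p of 0.0542. Defb47, a beta-defensin gene, was at 18 ± 18 against 0.183 ± 0.16 RPKM, also with an adjusted p of 0.0542. Uba1, an enzyme of ubiquitin activation, was at 50.6 ± 1.9 against 60.2 ± 1.8 RPKM with an adjusted p of 0.0958. limma called 2 genes, both higher, and 2006 had an unadjusted p under 0.05. When the fit held only these 2 groups, it called 1 gene. The count was 4 without HFD_STZ replicate 2 and 5 without HFD_STZ_AOS_FMT replicate 2. Kap lies on chromosome 6 at 133849851 to 133853762.

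**Figure D4:**
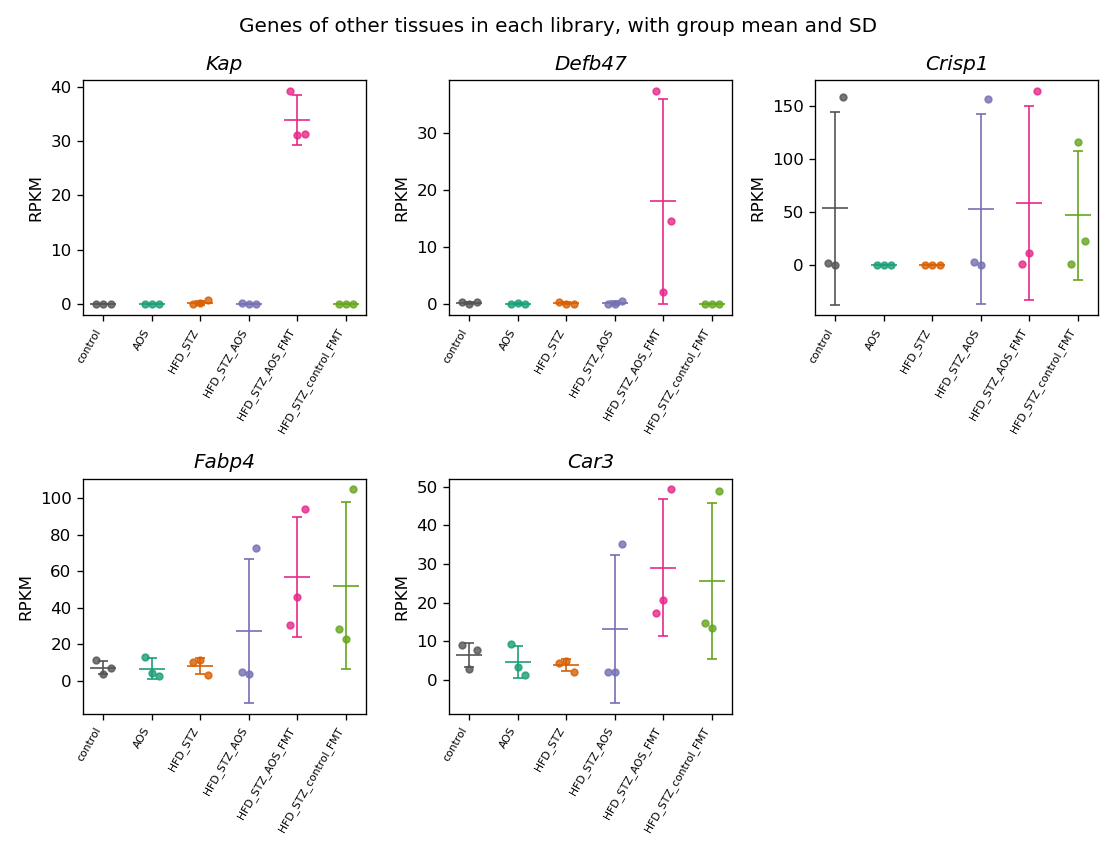
RPKM on the vertical axis of Kap, Defb47, Crisp1, Fabp4 and Car3 in each of the 18 libraries by group, where points are libraries, long bars are group means and whiskers are the SD (n = 3). The Kap libraries of HFD_STZ_AOS_FMT lay between 31.16 and 39.24 RPKM and the other 15 at or under 0.73, while Crisp1 was over 100 RPKM in 1 library of each of 4 groups.

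Camera with the preset correlation called 10 lists in HFD_STZ_AOS_FMT against HFD_STZ. Adipose tissue genes were higher in 13 of 13 members, with Fabp4 at 56.9 ± 33 against 8.31 ± 4.5 RPKM and Car3 at 29.1 ± 18 against 3.80 ± 1.5 RPKM. The list had an adjusted p of 1.85e-07, adjusted p = 0.217 with an estimated correlation and 7 members adjusted over the list alone. Epididymis genes were higher in 11 of 11 members at 2.55e-06, and adjusted p = 0.126 with an estimated correlation, with Cst11 and Wfdc15a adjusted over the list alone. The list had an adjusted p of 2.97e-06 without the 4 libraries high in Crisp1. Its members Cst8, Eppin, Wfdc10 and Wfdc15a reached 378.98, 38.92, 63.47 and 226 RPKM outside these 4 libraries. The call therefore need not mean epididymal RNA. Ribosomal protein genes were higher in 32 of 32 members at 8.37e-12 and oxidative phosphorylation genes in 32 of 34 at 1.27e-10, each with adjusted p = 0.173 with an estimated correlation. Adjusted over the list alone, 3 ribosomal genes (Rpl38, Rpl27 and Rpl19) and 5 oxidative phosphorylation genes passed. Elongating spermatid genes were higher in 26 of 29 members at 4.30e-08, and adjusted p = 0.298 with an estimated correlation, with 6 members, among them Prm3, Meig1 and Car2, adjusted over the list alone. Round spermatid genes were higher in 26 of 30 members at 1.79e-05, and adjusted p = 0.324 with an estimated correlation. Heat shock and immediate early genes were higher in 15 of 18 members at 0.000951, and adjusted p = 0.138 with an estimated correlation, with Cyr61 and Egr1, early responders to stimulation and handling, adjusted over the list alone. Antioxidant genes were higher in 18 of 28 members at 0.0256, and adjusted p = 0.537 with an estimated correlation. Cilium genes were lower in 20 of 27 members at 0.000951, and adjusted p = 0.217 with an estimated correlation, with 5 members adjusted over the list alone. Fatty acid oxidation genes were lower in 18 of 19 members at 0.00452, and adjusted p = 0.537 with an estimated correlation. In limma's test over all genes 0 members of the 10 lists passed. Unadjusted p values under 0.05 were found for 9 adipose, 5 epididymis, 16 ribosomal, 14 oxidative phosphorylation, 11 elongating spermatid, 8 round spermatid, 4 heat shock, 7 antioxidant, 12 cilium and 6 fatty acid genes. The fatty acid call was lost without HFD_STZ replicate 3 (0.0674). The antioxidant call was lost without HFD_STZ replicate 1 (0.0794), HFD_STZ replicate 2 (0.0845) or HFD_STZ_AOS_FMT replicate 2 (0.113), and with the length trend removed (0.231). The cilium list had an adjusted p of 0.0672 with that trend removed. The log2 changes of this comparison had a Spearman rho of -0.379 with transcript length. Removing the trend moved the medians from 0.138 to 0.0744 for ribosomal and from 0.133 to 0.0637 for oxidative phosphorylation genes. The elongating spermatid median moved from 0.104 to 0.0376, and the calls of these lists were kept.

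The transfer from control donors was read from HFD_STZ_control_FMT against HFD_STZ. Hsd3b6, a hydroxysteroid dehydrogenase of Leydig cells, fell to 9.69 ± 1.2 from 29.4 ± 5.1 RPKM, with a log2 change of -1.50 ± 0.16 and an adjusted p of 0.00114. Its paralog Hsd3b1, chosen after its values were seen, stood at 136 ± 7.4 against 95.3 ± 20 RPKM, with an adjusted p of 0.238. Hsd3b6 made up 6.69% ± 1.1 of the sum of both genes in HFD_STZ_control_FMT and 12.9% ± 2.6 in HFD_STZ_AOS_FMT. It made up 24.0% ± 6.3 in HFD_STZ, 26.9% ± 5.0 in HFD_STZ_AOS, 31.4% ± 7.1 in control and 31.5% ± 4.0 in AOS (n = 3 each). Reads may have been split between these near-identical genes, so both values are uncertain. Hsd3b6 lies on chromosome 3 at 98805504 to 98814443 and Hsd3b1 at 98852194 to 98859794. The nuclear receptor coactivator gene Ncoa1 was at 5.28 ± 0.17 against 7.51 ± 0.60 RPKM and the hedgehog receptor gene Ptch1 at 1.05 ± 0.040 against 1.70 ± 0.13 RPKM, each with an adjusted p of 0.0924. limma called 1 gene, and 2243 had an unadjusted p under 0.05. When the fit held only these 2 groups, it called 0 genes and Hsd3b6 had an adjusted p of 0.0712. Without HFD_STZ_control_FMT replicate 3 the count was 14, of which 10 were higher.

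Camera with the preset correlation called 8 lists in HFD_STZ_control_FMT against HFD_STZ. Adipose tissue genes were higher in 12 of 13 members, with an adjusted p of 2.00e-07, adjusted p = 0.321 with an estimated correlation and 5 members, among them Adipoq and Retn, adjusted over the list alone. Ribosomal protein genes were higher in 30 of 32 members at 1.33e-14 and oxidative phosphorylation genes in 32 of 34 at 2.70e-12, each with adjusted p = 0.237 with an estimated correlation. Adjusted over the list alone, 17 ribosomal and 7 oxidative phosphorylation genes passed, led by Rps18 and Cox4i1. Elongating spermatid genes were higher in 23 of 29 members at 1.67e-07, and adjusted p = 0.398 with an estimated correlation, with 3 members (Car2, Meig1 and Prm3) adjusted over the list alone. Round spermatid genes were higher in 23 of 30 members at 0.000229, and adjusted p = 0.552 with an estimated correlation, with 4 members, among them Tssk6 and Dkkl1, adjusted over the list alone. Heat shock and immediate early genes were higher in 14 of 18 members at 0.0130, and adjusted p = 0.261 with an estimated correlation. Epididymis genes were higher in 9 of 11 members at 0.0241, and adjusted p = 0.398 with an estimated correlation. Their adjusted p was 0.00320 without the 4 libraries high in Crisp1. Fatty acid oxidation genes were lower in 17 of 19 members at 0.0267, and adjusted p = 0.772 with an estimated correlation. In limma's test over all genes 0 members of the 8 lists passed. Unadjusted p values under 0.05 were found for 7 adipose, 19 ribosomal, 14 oxidative phosphorylation, 9 elongating spermatid, 7 round spermatid, 2 heat shock, 1 epididymis and 4 fatty acid genes. The epididymis call was lost without HFD_STZ replicate 2 (0.0504) or HFD_STZ_control_FMT replicate 2 (0.0779), and with the length trend removed (0.515). The fatty acid call was lost without HFD_STZ replicate 3 (0.136) or HFD_STZ_control_FMT replicate 3 (0.163), and the heat shock call without HFD_STZ replicate 2 (0.0589) or HFD_STZ_control_FMT replicate 3 (0.118). With the length trend removed, the medians moved from 0.160 to 0.101 for ribosomal and from 0.126 to 0.0722 for oxidative phosphorylation genes. The elongating spermatid median moved from 0.103 to 0.0604, and the calls of these lists were kept.

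The donor difference was read from HFD_STZ_AOS_FMT against HFD_STZ_control_FMT. Kap was at 33.9 ± 4.6 RPKM and was listed at 0 in all 3 HFD_STZ_control_FMT libraries, so no fold is given, and its adjusted p was 4.62e-12. Defb47 was higher at 18 ± 18 against 0.0600 ± 0.052 RPKM with an adjusted p of 0.0447. Hsd3b6 stood at 19.4 ± 1.3 against 9.69 ± 1.2 RPKM, with an adjusted p of 0.0973. The glucocorticoid-responsive gene Tsc22d3 was at 4.62 ± 0.21 against 6.63 ± 0.31 RPKM with an adjusted p of 0.132. limma called 3 genes, all higher, and 635 had an unadjusted p under 0.05, below the 693.7 expected by chance. Without HFD_STZ_AOS_FMT replicate 2 the count was 5. Defb47 lies on chromosome 14 at 62998077 to 63001160. Its call was lost in 10 of 14 other settings, with adjusted p values of 0.0709 and 0.407 without HFD_STZ_AOS_FMT replicates 1 and 3 and of 0.266, 0.274 and 0.239 without HFD_STZ_control_FMT replicates 1, 2 and 3.

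For the donor difference, camera with the preset correlation called 3 lists. Sertoli cell genes were higher in 21 of 28 members, with Rhox8 at 15 ± 1.1 against 12.5 ± 1.0 RPKM, at an adjusted p of 0.000240 and adjusted p = 0.955 with an estimated correlation. Leydig cell genes were higher in 11 of 20 members at 0.0385, and adjusted p = 0.987 with an estimated correlation, with Hsd3b6 the 1 member adjusted over the list alone. Epididymis genes were higher in 9 of 11 members at 0.0342, and adjusted p = 0.955 with an estimated correlation, with Cst11 the 1 member adjusted over the list alone. Their adjusted p was 0.0327 without the 4 libraries high in Crisp1. In limma's test over all genes 0 members of these lists passed, and 7 Sertoli, 3 Leydig and 2 epididymis genes had an unadjusted p under 0.05. The Sertoli call was lost without HFD_STZ_AOS_FMT replicate 2 (0.0546), and the Leydig call without that library (0.320) or HFD_STZ_control_FMT replicate 3 (0.216). The epididymis call was lost without HFD_STZ_AOS_FMT replicate 1 (0.181) or 3 (0.291), or without HFD_STZ_control_FMT replicate 1 (0.0635) or 3 (0.164). Without HFD_STZ_AOS_FMT replicate 1 camera called 6 lists.

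Whether each treatment moved genes back towards control was tested on the covariance of the treated change with the change from control to HFD_STZ, less the part that the shared HFD_STZ libraries give with no effect. The excess was -0.000684 for HFD_STZ_AOS, -0.00799 for HFD_STZ_AOS_FMT and -0.00866 for HFD_STZ_control_FMT, where a negative value is a return. In 100 regroupings of the libraries' deviations the permutation p values were 0.911, 0.188 and 0.158, so none passed. A full return would give an excess near minus the variance of the HFD_STZ effect, which was estimated at 0.00591. The excess had an SD of 0.00741 over the regroupings, so the test could hardly show even a full return. Its p values therefore do not count against a return. Of the 1151 genes with an unadjusted p under 0.05 between HFD_STZ and control, 57.4% in HFD_STZ_AOS, 86.3% in HFD_STZ_AOS_FMT and 85.9% in HFD_STZ_control_FMT changed in the opposite direction. Unchanged groups gave a median of 95.2% because the HFD_STZ libraries are shared, with a lowest value of 67.9% in 98 draws. The share of HFD_STZ_AOS lay below all of these draws, while 8 draws lay at or below the shares of each microbiota group. These draws hold no difference between HFD_STZ and control, and a diet effect that stays in place was not simulated. The shares therefore cannot decide for or against a return in any of the groups. Fitm1 was at 24.9 ± 11 RPKM in HFD_STZ_AOS, 8.75 ± 0.83 in HFD_STZ_AOS_FMT and 8.15 ± 0.81 in HFD_STZ_control_FMT, between the 5.80 ± 1.1 of control and the 17.0 ± 3.2 of HFD_STZ in both microbiota groups. Cyp21a1 stood at 9.27 ± 2.3 and 8.99 ± 3.1 RPKM in the microbiota groups, against 8.37 ± 1.3 in HFD_STZ and 3.68 ± 1.1 in control. These levels of Fitm1 and Cyp21a1 in the microbiota groups were chosen after their values were seen.

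A test of any difference among the 6 groups, also added after the planned comparisons, called 6 genes in limma's F test, with 2923 at an unadjusted p under 0.05. Kap (adjusted p 1.10e-11), Hsd3b6 (0.000523) and Fitm1 (0.0216) led them, followed by Ssbp4 (0.0323) and Hddc3 (0.0347), which were chosen after their values were seen. Ssbp4 was lowest in control at 9.35 RPKM and highest in HFD_STZ_AOS at 13.5 RPKM. The count was 36 without AOS replicate 2, 14 without HFD_STZ replicate 2, 157 without HFD_STZ_AOS replicate 2, 117 and 12 without HFD_STZ_AOS_FMT replicates 1 and 3, and 11 without HFD_STZ_control_FMT replicate 1. It was 3 without HFD_STZ_AOS replicate 1 or HFD_STZ_control_FMT replicate 2 or 3.

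Libraries also differed in genes of neighbouring tissue. Crisp1, a secreted protein of the epididymis, was at 158.77 RPKM in control replicate 3, 156.69 in HFD_STZ_AOS replicate 3, 164.71 in HFD_STZ_AOS_FMT replicate 3 and 116.64 in HFD_STZ_control_FMT replicate 2. It was at 23.11 in HFD_STZ_control_FMT replicate 3, at 11.49 in HFD_STZ_AOS_FMT replicate 2 and at or under 2.93 RPKM in the other 12 libraries. The fat cell gene Fabp4 was at 30.76, 46.19 and 93.87 RPKM in the libraries of HFD_STZ_AOS_FMT and 28.69, 22.71 and 104.95 in those of HFD_STZ_control_FMT. It was at 72.55 RPKM in HFD_STZ_AOS replicate 3 and at or under 13.17 in the other 11 libraries, with 6.86 in control replicate 3.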

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

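The tests of Crisp1 against treatment, of epididymal genes, of the ratio of Kap to Crisp1, of the length trend and of AOS as its only cause, and the omission of the 4 libraries high in Crisp1, were chosen only after the results had been seen. A difference between groups was found for 6 gene lists whose change with AOS differed between the diet with STZ and the plain state, by the interaction in camera with a preset correlation. The adjusted p was 1.62e-08 for interferon response, 0.00202 for ribosomal proteins, 0.0217 for extracellular matrix and 0.0170 for each of epididymis, cholesterol biosynthesis and antioxidant defence genes. With an estimated correlation they gave adjusted p = 0.408, adjusted p = 0.891, adjusted p = 0.891, adjusted p = 0.599, adjusted p = 0.891 and adjusted p = 0.891 in that order. The interferon list was lower in 13 of 14 members, and the others were higher, in 26 of 32 ribosomal, 18 of 19 matrix, 9 of 11 epididymis, 20 of 24 cholesterol and 20 of 28 antioxidant members. Adjusted over the list alone, Txn1 (0.58 ± 0.14) and Gstp1 (0.69 ± 0.19) passed in the antioxidant list, and limma called 0 members over all genes, with 7 ribosomal, 0 matrix, 1 epididymis, 1 cholesterol and 5 antioxidant genes at an unadjusted p under 0.05.

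Without the 4 libraries high in Crisp1, the interaction's adjusted p was 3.88e-07 for interferon and 0.0217 for ribosomal genes, and 0.217, 0.891, 0.426 and 0.108 for epididymis, matrix, cholesterol and antioxidant genes. Camera called 3 lists without control replicate 3, 1 without HFD_STZ replicate 1 and 10 without control replicate 2. Without HFD_STZ replicate 1 the adjusted p was 0.0925 for ribosomal and epididymis, 0.222 for cholesterol, 0.115 for matrix and 0.0966 for antioxidant genes. Without HFD_STZ_AOS replicate 3 it was 0.109 for epididymis and cholesterol, 0.814 for matrix and 0.0872 for antioxidant genes. Without control replicate 3 it was 0.0909 for epididymis and matrix and 0.116 for cholesterol genes. It was 0.0832 for matrix and antioxidant genes without AOS replicate 3, and 0.0876 for antioxidant genes without control replicate 1.

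Crisp1 stood at over 100 RPKM in 4 libraries of 4 groups. The control library reached 0.964 of the highest treated library, which argues against diet, AOS or microbiota as its source. RNA of epididymis could be the source, but only 30% of the other epididymis genes above 5 RPKM (3 of 10: Adam7, Rnase9 and Spink8) had their 4 highest values in these libraries. That share lies between the bounds set for and against it, which keeps the source open. Cst8, Eppin, Wfdc10 and Wfdc15a reached 379, 38.9, 63.5 and 226 RPKM in the other 14 libraries. With levels this high there, they could not show a small share of epididymal RNA. Gpx5 and Cst11 reached 22.21 and 11.22 RPKM in the other 14 libraries, against at most 10.04 and 5.72 in the 4. Cd52, which is not on the list, followed Crisp1, at 80.99 to 139.53 RPKM in the 4 libraries and at most 20.25 elsewhere.

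Kap stood apart in all 3 HFD_STZ_AOS_FMT libraries. The same epididymal RNA is argued against, since the ratio of Kap to Crisp1 differed by 208 times between these libraries. Of 39 detected genes of a kidney list, 10.3% (Slc22a6, Keg1, Dnase1 and Cdh16) were higher in all 3 libraries than in each of the other 15, where 0.0478 genes were expected by chance. This share, 10.3%, decides neither between kidney RNA in the samples nor a rise of Kap in the testis alone, so these cannot be told apart, and a response to the transfer stays open. Of the 17 kidney genes with a median of 0.1 RPKM or less elsewhere, 16 had a higher median in the 3 libraries, a count added after the first result, while abundant testis levels hide a small share for genes such as Pdzk1.

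Short transcripts stood higher and long ones lower in every group other than control and HFD_STZ. AOS as the only cause is argued against, because HFD_STZ_control_FMT, with no AOS in its label, had a rho of -0.345 with length against HFD_STZ and of -0.375 against control. Removing the trend left 0 of 325 calls of the AOS main effect, but the median size of these changes only moved from 0.195 to 0.141 with a median SE of 0.0418 before and 0.0382 after. A yield by length that differs between libraries therefore cannot be told apart from a change in the genes. A higher share of elongating spermatid RNA may also be involved, and the list kept 0.323 of its median after the removal, between the bounds set for and against it.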

How the results depend on the processing

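The settings chosen only after the data were seen were the removed length trend, the omission of the 4 libraries high in Crisp1, leave-one-out of the gene lists, and all settings of the main effects and the F test. Where a value moved below, the cause was not tested.

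Without a filter on low values, 20595 genes were tested. limma then called 1 gene for HFD_STZ_AOS and 16 for HFD_STZ_AOS_FMT against HFD_STZ, 4 for HFD_STZ_control_FMT against HFD_STZ, 11 between the donors, 205 for the main effect of HFD_STZ, 142 for that of AOS and 18 in the F test. With only the groups compared, it called 1 for HFD_STZ_AOS_FMT and 0 for HFD_STZ_control_FMT against HFD_STZ (2380 at an unadjusted p under 0.05), 6 between donors, 133 for HFD_STZ and 565 for AOS as main effects. A pseudocount of 0.1 gave 4 and the removed length trend 5 for HFD_STZ_AOS_FMT against HFD_STZ, and the latter gave 0 for the main effect of AOS. Without the 4 libraries, the counts were 2 for HFD_STZ_AOS against HFD_STZ, 36 for the main effect of HFD_STZ and 76 for that of AOS, and the return of HFD_STZ_AOS was 0.000226.

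In camera with an estimated correlation, 0 lists were called in each of the 9 comparisons. fry called 0 in HFD_STZ against control, 2 in HFD_STZ_AOS and 5 in HFD_STZ_AOS_FMT against HFD_STZ, 3 in each main effect and 0 in the other 4. With the length trend removed, camera called 4 lists for HFD_STZ_AOS against HFD_STZ. Without the 4 libraries it called 12 there, 7 between donors, 2 for the interaction and 8 for the main effect of AOS.

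With 1 library left out, counts of genes ranged from 2 to 5 for HFD_STZ_AOS_FMT and 1 to 14 for HFD_STZ_control_FMT against HFD_STZ, 2 to 5 between donors, 0 to 3 for AOS against control, 110 to 695 and 0 to 374 for the main effects of HFD_STZ and AOS and 3 to 157 in the F test. HFD_STZ against control, HFD_STZ_AOS against HFD_STZ and the interaction stayed at 0 in limma. Counts of lists ranged from 4 to 5 (HFD_STZ against control), 6 to 12, 9 to 13 and 6 to 12 (HFD_STZ_AOS, HFD_STZ_AOS_FMT and HFD_STZ_control_FMT against HFD_STZ), 2 to 6 (donors), 6 to 9 (AOS against control), 1 to 10 (interaction), 4 to 10 and 5 to 9 (main effects of HFD_STZ and AOS). The return ranged from -0.00296 to 0.00265 for HFD_STZ_AOS, from -0.0115 to -0.00367 for HFD_STZ_AOS_FMT and from -0.0115 to -0.00424 for HFD_STZ_control_FMT. The sign of the first turned without control replicate 3, HFD_STZ replicate 2 or HFD_STZ_AOS replicate 3.

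Replicate numbers were shared by the groups, and the deviations of same-numbered samples had correlations of -0.138 to 0.0707 in 17 of 18 pairs and 0.279 for replicate 1 of the 2 microbiota groups. In 3 of the 18 pairs both samples correlated best with their own number. With the replicate number as a block, the count became 2 for HFD_STZ_control_FMT against HFD_STZ and 10 in the F test, and every other count of genes stayed within 1.5 times. The Leydig list for the donor difference then had an adjusted p of 0.0592. Median-ratio scaling moved the median of all genes by at most 0.0293. Of 5915 values of named genes under the alternatives, 5402 kept their side of the threshold, 455 were no longer past the threshold, 58 were newly past it and 0 called values changed sign. Of the 4733 values past the threshold in neither fit, 88 had the other sign. RPKM rounded to hundredths limits genes near the level of a few reads, such as Kap outside HFD_STZ_AOS_FMT.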

Other observations

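The tests of genes called between HFD_STZ_AOS and AOS and of other splits for the main effects and the F test were chosen only after the planned results had been seen. A read-out of the return free of shared libraries used 75 genes called between HFD_STZ_AOS and AOS, 67 higher and 8 lower. In HFD_STZ against control 90.7% of them had the same direction. Against HFD_STZ, 77.3% moved towards control in HFD_STZ_AOS_FMT and 76.0% in HFD_STZ_control_FMT, with median signed changes of -0.10 and -0.12 on the log2 scale. Over all genes the correlations with the change between HFD_STZ_AOS and AOS were 0.0556 and 0.0447, of the opposite sign to a return. In 0 of 100 draws of unchanged groups was the median as large, and with the length trend removed the 75 genes with the smallest p, of which only 4 were called, gave shares of 85.3% and 78.7%. The draws held no difference between groups. They therefore cannot tell a return from another shift between HFD_STZ and the microbiota groups. Over all tested genes the median log2 change against HFD_STZ was -0.020 in HFD_STZ_AOS_FMT and -0.028 in HFD_STZ_control_FMT. A partial return of these 75 genes, not of all genes, in both microbiota groups is left as a hypothesis. The planned covariance test of the same question did not pass, and it could hardly show even a full return. A part of the read-out could come from the HFD_STZ libraries, which both microbiota comparisons share, and the donors' own difference in return was not tested.

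Other splits of the same samples bear on the counts of called genes. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real counts were 0, 0, 2, 1, 3 and 0 for HFD_STZ against control, HFD_STZ_AOS, HFD_STZ_AOS_FMT and HFD_STZ_control_FMT against HFD_STZ, the donors and AOS against control, and the highest other splits gave 0, 1, 1, 0, 1 and 1. As many genes as the real split came in 10, 10, 1, 1, 1 and 10 of the 10 splits, which a real count of 0 fixes at 10. For the main effects, only the real split among 100 splits of the 12 samples reached the real count. The counts were 396 against a highest other of 214 for HFD_STZ, and 325 against 11 for AOS. This argues against 4 groups with no difference of any kind. It does not test either main effect by itself, because the other splits leave the real group differences in the spread, which can lower their counts. In the F test 2 of 100 splits of the 18 samples, the real one among them, reached the real count of 6, with a highest other of 20. For the interaction the real count of 0 is reached by all 100 of 100 splits, so this says nothing about chance. The highest other split called 323 genes. The splits did not remove the main effects of HFD_STZ and AOS, so a split can place these on the interaction. The 323 genes therefore need not point to another structure of the samples, which was not tested. At an unadjusted p under 0.05, 46 of 100 splits gave at least the 640 genes of the real one.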
